A study of Escherichia coli BL21(DE3) with 11 samples.

How the data were processed

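Record-seq reads the past transcription of a bacterium from DNA. The reporter was Escherichia coli BL21(DE3) with the plasmid pFS_0453. It copies fragments of its own RNA as spacers into a CRISPR array on the plasmid. Sequencing of the spacers counts the transcripts they came from. Per the labels' protocols, the reporter was given to mice by mouth 11 hours before sampling. Faeces (100 mg per mouse) were suspended in buffer with 10 mM Tris-EDTA and spun for 1 minute at 200 x g, and plasmid was purified from the bacterial pellet. All 11 libraries came from day 5 and fell into 4 groups by their titles: Con (3 libraries), DSS (3), Lc (3) and DSLc, which is DSS with Lc (2). DSS is dextran sulfate sodium, a polymer that injures the colon lining, and the series describes a feed with Lactobacillus crispatus, taken here as the Lc of the titles. The series text also names DNBS, another inducer of colitis, and no sample with it was analysed here.

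The authors deposited a table of counts per gene, 1 column per library, with gene positions on NC_012947.1, the BL21(DE3) chromosome, per the file headers. FastQC, Trimmomatic, Bowtie2, Subread and featureCounts are named in the submitters' processing notes without versions. The strand setting, the treatment of reads that match several places and the removal of duplicates are not given in the sources used here, so counts of near-identical genes, overlapping genes and antisense partners are uncertain. No value column was left unmapped. Gene names were used as deposited. Of 4306 names, 3579 matched a symbol of the K-12 MG1655 annotation, used for names only, 336 matched through an older symbol and 391 did not match. Current symbols are given in parentheses.

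Library totals ran from 12147 to 23401 counts, shallow for 4306 genes, and 1082 genes had no count in any library. A count of 0 in a library allows a share of up to 0.0128% to 0.0247% (3 counts of the total), and this floor covers counting error only. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 5 and a minimum total of 15, which left 972 genes holding 86.0% of the counts. Libraries were scaled by TMM, all 11 were fitted together with group as the only term, and each comparison was tested with the quasi-likelihood F-test (robust) and Benjamini-Hochberg adjustment at 0.05. Standard errors were taken as the log2 fold change over the square root of F. A total of 38 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternatives, and the 21 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Profiles were compared by PERMANOVA on Euclidean distances of log2 CPM (prior count 2) with 100000 permutations, and library totals by exact permutation tests.

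The rule for named genes took, per comparison, the 15 genes higher and the 15 lower with the smallest p among those that passed, the 5 with the smallest unadjusted p where fewer than 5 passed in a direction, up to 4 members of each list discussed, and the 5 genes with the largest mean share of counts. The lists discussed were those that passed camera and 7 fixed ones: anaerobic respiration, OxyR oxidative stress, acid resistance, iron acquisition, mucus and host sugar catabolism, ribosomal proteins and RpoS general stress. Outside DSS against Con, list members are given as examples only with an unadjusted p under 0.05, a limit set after their values were seen, which left out 67 examples.

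Replicates were compared before averaging. Lc 2 and Lc 3 agreed within sampling noise (chi-square over 845 genes, ratio to its degrees of freedom 1.01, p = 0.437), while the other Lc pairs differed, and they were counted as 1 sample in every mean and SD. That test over many genes did not show their difference in rRNA share. It was 11.4% in Lc 2 (95% interval 11.0 to 11.8) and 13.3% in Lc 3 (12.8 to 13.8). The only DSLc pair also agreed within sampling noise (ratio 0.944), with no other pair of that group to compare, and was kept as 2 samples. Agreement also crossed groups: the ratio was 0.940 for Lc 2 and DSLc 2, within noise, and 0.825 for Lc 3 and DSLc 1. The latter pair was closer than independent counts usually are (chi-square upper-tail p = 0.9998), so these 2 libraries may not be independent. The model kept all 11 libraries, and alternatives chosen after seeing the data summed the pairs. The labels speak of faeces per mouse but do not number the mice, so p-values measure only the spread between these libraries.

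All Con and DSS pairs differed beyond counting noise (ratios 1.50 to 1.93). The common negative binomial dispersion was 0.0152. The median quasi-likelihood dispersion, which is relative to the fitted negative binomial variance, was 0.814. The replicate numbers of the titles did not pair the libraries across groups. The second number of the library name in the labels did: deviations from the group means correlated at 0.36 to 0.53 in all 9 pairs that share it, and 7 of 7 such libraries correlated best with their own number. Numbers 3 and 5 recur, and 4 libraries, 1 per group, have a number of their own (Con 3, DSS 1, Lc 2 and DSLc 2). As an alternative chosen after seeing the data, the number was a block in a fit of only the 7 libraries whose number recurs, of which 1 is a DSLc library. That fit also leaves out DSS 1 and Con 3. A call lost there can be due to the block or to the libraries left out, which it cannot tell apart. A block over all 11 libraries pooled the 4 others as 1 level although they share no number, so its counts are given only among the alternatives. What the number stands for is not given in the sources used here.

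Alternatives were TMMwsp factors, scaling by total count, DESeq2 1.42.0, a minimum count of 10, no filter, a fit of only the groups compared, the title's replicate number as a block, no rRNA genes, a non-robust dispersion and each library left out. Added after seeing the data were the pooled library-name block, a fit of only the 7 libraries whose number recurs, summed near-duplicate libraries, summed rRNA copies and the edgeR likelihood ratio test. Tested on simulated data for DSS against Con over 894 genes, the F-test recovered 75.8% of 66 genes changed 4-fold, 19.4% of 67 changed 2-fold and 5.97% of 67 changed 1.5-fold, with 1 unchanged gene called. For DSLc against DSS (899 genes) it recovered 74.2%, 14.9% and 4.48%, with 5 unchanged genes called, and for Lc against Con (880 genes) 80.3%, 29.9% and 10.4%, with 1. The simulated libraries were independent, and depth and number of libraries were not varied. Camera recovered both lists raised 1.5-fold in simulated DSS libraries and called no other list. The genes were simulated independently, so lists of correlated members, such as rRNA copies, were not covered.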

Results

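The reporter's transcript record was read from the faeces of mice in 4 groups on day 5: Con (3 libraries), DSS (3), Lc (3) and DSLc, which combined both treatments (2). Totals were 12570 to 16572 counts in Con, 16031 to 21680 in DSS, 16294 to 23401 in Lc and 12147 to 17661 in DSLc, and between 2106 and 2647 of 4306 genes had a count in a library. Lc 2 and Lc 3 agreed within sampling noise across genes, though not in rRNA share, and were counted as 1 sample in means and SDs. Library totals did not separate any pair of groups (2-sided exact permutation tests over 6 pairs, lowest p = 0.2, where 0.1 is the smallest p the design allows). The lowest such p for the number of genes with a count was 0.1, for Lc against Con.

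The largest mean shares of counts were those of the 23S rRNA genes rrlG (4.92% ± 1.13, SD, n = 10 samples) and rrlD (4.87% ± 1.06), followed by raiA, a ribosome-hibernation factor (2.20% ± 0.280), gatY, an aldolase of galactitol use (1.62% ± 0.0857), and dnaK, a chaperone (1.30% ± 0.0802). Near-identical rRNA copies can share reads, so the split between rrlG and rrlD is uncertain. The 4 groups differed in whole profile (pseudo-F = 2.22, one-sided permutation p = 0.00065), and group accounted for 48.7% of the summed squared distance. Random labels also account for a part of this distance, which was not computed, so 48.7% is not the share due to treatment. The second number of the library name, with single numbers pooled as 1 of 3 levels, accounted for 29.7% (one-sided permutation p = 0.0243). The part that random labels account for depends on the number of levels, so 29.7% and 48.7% cannot be compared directly.

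DSS against Con asks what DSS changed in the record of the reporter without Lc. The aspartase gene aspA rose from 11790 ± 1685 to 18749 ± 839 CPM (mean ± SD, n = 3 in each group), and tnaA, the tryptophanase that releases indole, from 10151 ± 1230 to 15838 ± 1593 CPM. The carbonic anhydrase gene can rose 3.63-fold, from 870 ± 83.6 to 3121 ± 1222 CPM, and the ribosomal protein gene rpmH fell from 13891 ± 1267 to 9253 ± 1570 CPM. Of 972 genes tested, 71 rose and 37 fell, and 292 had an unadjusted p under 0.05. All 3 DSS libraries lay above all 3 Con libraries for 68 of the 71 and below them for 34 of the 37. The same libraries made these calls, so that separation follows from the selection and is no separate support. Of all tested genes 29.1% had such a separation, where chance gives 10%.

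Among the 15 higher genes with the smallest p, log2 fold changes were 1.86 ± 0.28 (SE) for can (adjusted p = 0.000694, edgeR quasi-likelihood test), 0.67 ± 0.13 for aspA (adjusted p = 0.00329) and 0.64 ± 0.13 for tnaA (adjusted p = 0.00385). The 23S genes rrlG and rrlD rose by 0.79 ± 0.15 and 0.78 ± 0.15. Respiratory genes were ybgE (1.97 ± 0.36) and ybgT (cydX, a small subunit of cytochrome bd oxidase, 1.97 ± 0.39), which overlap at position 732964 of NC_012947.1 and have uncertain counts, and sdhB, the iron-sulfur subunit of succinate dehydrogenase (1.84 ± 0.40). The helicase gene ruvB had 3.37 ± 0.60. The others were ydcL (2.40 ± 0.42), yjjK (ettA, 2.39 ± 0.50), ycbL (gloC, 2.32 ± 0.49), tas (1.14 ± 0.23), the glycolytic gene eno (1.02 ± 0.21) and smpA (bamE, of the outer-membrane assembly machine, 0.88 ± 0.19). Levels were low for ruvB, with 76.2 ± 13.0 CPM in Con and 830 ± 456 CPM in DSS. Its Con level lies under the floor of 3 counts in these libraries (181 to 239 CPM of all counts). That SD therefore does not measure the spread between replicates, and the rise rests on very few Con counts.

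Among the 15 lower genes with the smallest p, the largest falls were those of xdhA, a putative xanthine dehydrogenase subunit (log2 fold change -3.28 ± 0.76, adjusted p = 0.00808, edgeR), mog of molybdenum cofactor synthesis (-2.70 ± 0.71), the histidine transport gene hisP (-2.26 ± 0.63) and the lipid A gene lpxB (-2.21 ± 0.56). The fatty acid genes fabZ and fadR had -1.73 ± 0.40 and -1.71 ± 0.43, and lpd, the lipoamide dehydrogenase of pyruvate dehydrogenase, had -1.14 ± 0.26. Values were -2.03 ± 0.54 for qseD (hypT), -1.89 ± 0.51 for ilvD of branched-chain amino acid synthesis and -1.64 ± 0.43 for csrD. They were -1.50 ± 0.40 for ribE, -1.50 ± 0.39 for cvrA, -1.24 ± 0.34 for seqA, -1.17 ± 0.30 for yibL and -0.60 ± 0.13 for rpmH. Levels of xdhA, mog and hisP are not given here. Between DSS 2 and Con 1, xdhA and hisP had the same log2 difference (-1.21), as genes with very few counts can. The sizes of these falls are therefore uncertain. None of the 15 passed without DSS 1. In the 7 libraries whose second library-name number recurs, with that number as a block, only rpmH, fabZ and csrD passed, and xdhA had adjusted p = 0.187 (edgeR).

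Of the 21 lists tested, only ribosomal RNA passed in DSS: 7 of 9 tested members rose (8 adjusted over the list alone), among them rrlE (1.45 ± 0.36) and rrlC (1.32 ± 0.33). Camera gave adjusted p = 4.63e-08 at the preset correlation of 0.01, and adjusted p = 0.707 with an estimated correlation. Fry gave adjusted p = 0.0575. The members are copies of the 23S and 16S genes that can share reads, so they are not independent measurements. The preset correlation treats them as nearly independent. The 23S share was 8.41% ± 2.10 in Con and 13.2% ± 1.04 in DSS (SD, n = 3 each), and with the copies summed the 23S log2 fold change was 0.82 ± 0.15 (adjusted p = 0.00217, edgeR). The 16S share was 2.31% ± 0.27 in Con and 2.46% ± 0.26 in DSS, and did not pass (0.26 ± 0.12, adjusted p = 0.127, edgeR). Ribosomal proteins went both ways, with 3 of 42 higher (rpsH at 1.85 ± 0.53 and rpmE at 0.70 ± 0.20) and 3 lower (rpmH and rpmC, the latter at -1.55 ± 0.45). Of 9 OxyR genes 1 rose, oxyR itself (1.85 ± 0.54, adjusted p = 0.0275, edgeR), with dps at 1.63 ± 0.56 (adjusted p = 0.0563). In that list sufD (1.17) and trxB (-0.96) did not pass. Its values were positive for 6 genes and negative for 3, with a median of 0.08. Of 18 genes for mucus and host sugars 2 fell, manZ (-2.31 ± 0.64) and manY (-1.77 ± 0.53), neighbours of 1 mannose transporter operon. Their list also holds eda (-1.20) and fucK (-0.91), which did not pass. Of 8 RpoS genes 1 fell, cbpA (-1.54 ± 0.50), while glgS (0.43) and rpoS (0.58) did not pass. The tested members of anaerobic respiration (dcuA, 0.68 ± 0.39, and napC, 0.33 ± 0.33), acid resistance (cadC, -0.94 ± 0.85) and iron acquisition (entD, -0.44 ± 0.50) did not pass. In the 7 libraries with the number as a block oxyR (adjusted p = 0.0525, edgeR), rpsH, rpmE, rpmC, cbpA and rrlE did not pass, while manZ, manY and rrlC did. There dps had 0.53 ± 0.45 (adjusted p = 0.738, edgeR) and dcuA 0.25. The excess of oxyR over the Con mean was 228, 953 and 309 CPM in DSS 1, 2 and 3.

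The DSS count depended on single libraries: 12 genes passed without DSS 1 (12 higher, 0 lower), 25 without Con 3 (19 and 6) and 54 without DSS 2 (42 and 12), and DESeq2 called 15 (12 and 3). None of the 37 lower genes passed without DSS 1. The genes can, aspA, tnaA, rrlG and rrlD passed without DSS 1, without Con 3, with DESeq2 and in the 7 libraries whose second library-name number recurs. Those 7 also lack DSS 1 and Con 3, so that fit is not support separate from leaving out each of them. With total count scaling, which lowers the median log2 fold change of all genes by 0.17 relative to TMM, 61 genes were higher and 83 lower. Within the pair of libraries numbered 3, 70 of the 71 higher and 37 of the 37 lower genes kept their direction, and within the pair numbered 5, 71 and 36 did, though these libraries also entered the pooled test. In the fit of only the 7 libraries whose number recurs, with the number as a block, 31 rose and 7 fell, and 29 of these 38 were among the 108.

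**Figure D1:**
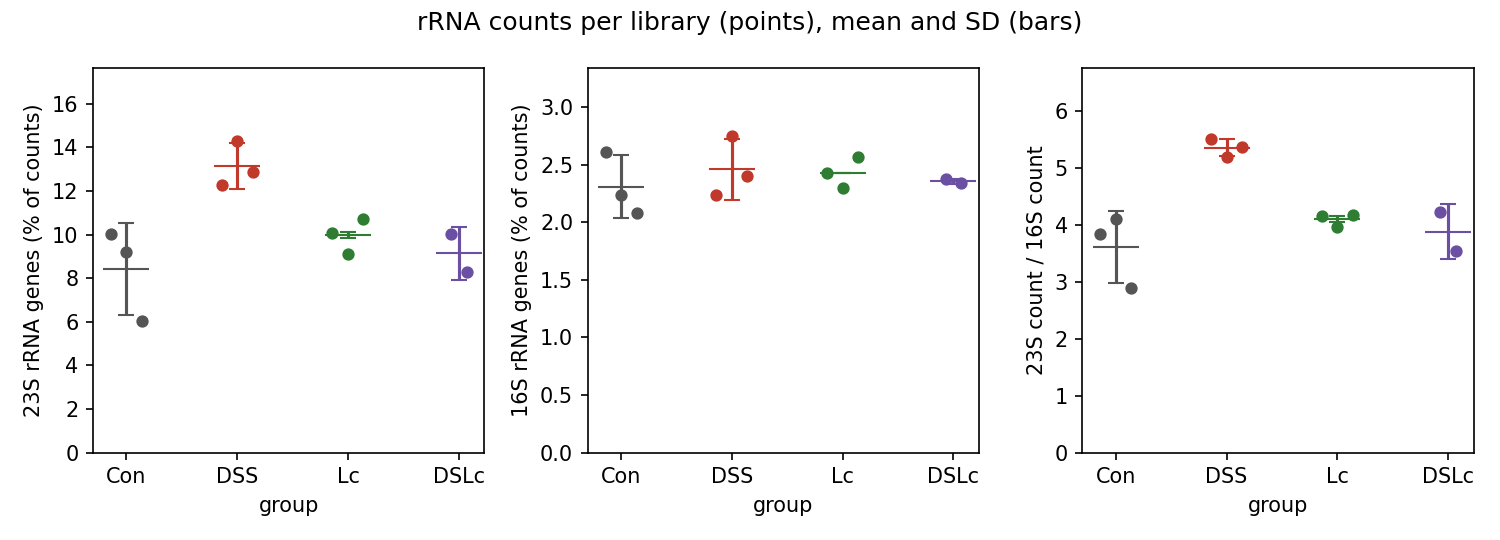
Share of counts in 23S rRNA genes (left, percent), in 16S rRNA genes (middle, percent) and the ratio of both counts (right), with a point per library and bars for the mean and SD per group, where Lc 2 and Lc 3 count as 1 sample. The 3 DSS libraries have ratios from 5.20 to 5.50, above the highest Con library at 4.11.

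**Figure D2:**
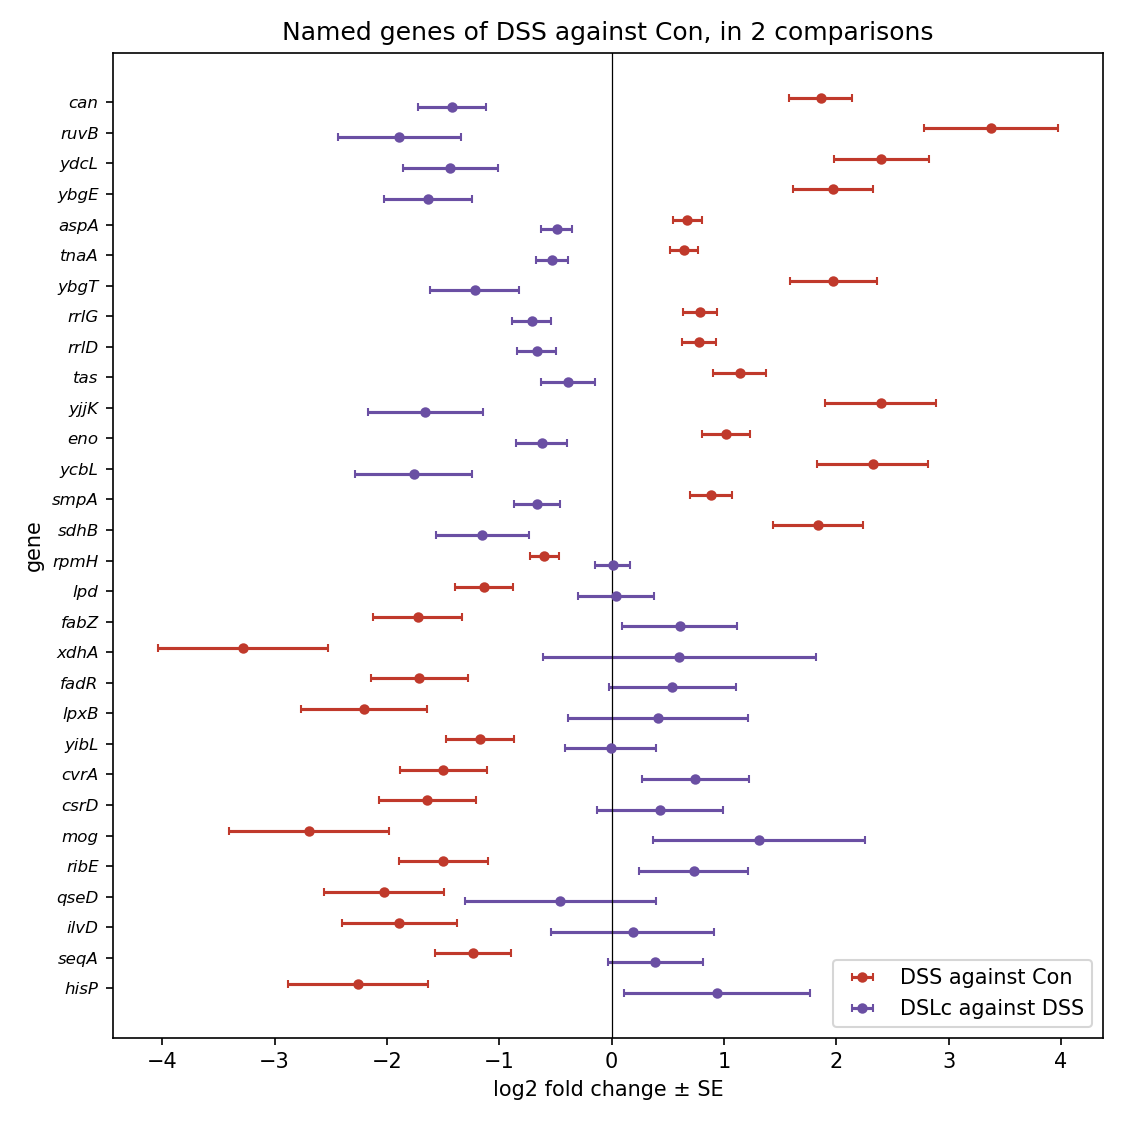
Log2 fold change with its SE (horizontal axis) of the 15 higher and 15 lower named genes of DSS against Con, for that comparison and for DSLc against DSS. Both comparisons use the same DSS libraries with opposite sign, which pulls the points of a gene to opposite sides of 0.

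Lc against Con asks what the Lc feed changed in the record without DSS. The mannose transporter gene manX, the small heat-shock gene ibpA and tas rose, and the ribosomal protein gene rpmH, erpA of iron-sulfur insertion and the cell-wall gene murC fell. The manX level was 664 ± 108 CPM in Con (SD, n = 3) and 1502 ± 24.3 CPM in Lc (n = 2), and ibpA went from 1465 ± 166 to 2646 ± 141 CPM. Of 972 genes, 6 rose and 8 fell. Among them, tas, ibpA, rpmH, qseD, yibL, ilvD and fadR also passed in DSS against Con, in the same direction. Both comparisons use the same Con libraries, so these shared calls are not separate findings and cannot be assigned to the Lc feed alone.

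The higher genes in Lc had log2 fold changes of 2.55 ± 0.62 (yjfN), 1.73 ± 0.43 (yaiL), 1.17 ± 0.30 (mdoD, now opgD, of periplasmic glucan synthesis), 1.15 ± 0.29 (manX), 1.04 ± 0.23 (tas) and 0.88 ± 0.20 (ibpA). The lower genes were qseD (hypT, -3.07 ± 0.59, adjusted p = 0.0255, edgeR), the cell-wall gene murC (-2.48 ± 0.64), ilvD (-1.96 ± 0.50), fadR (-1.60 ± 0.41) and yibL (-1.37 ± 0.30). Also lower were erpA of iron-sulfur insertion (-1.18 ± 0.27), the nucleoid gene hupB (-0.54 ± 0.14) and rpmH (-0.52 ± 0.13). The highest adjusted p among the 14 was 0.0451. Of 18 genes for mucus and host sugars 1 rose, manX, while fucK (-1.72 ± 0.47), gntK (1.28 ± 0.39) and nanS (1.79 ± 0.57) did not pass. Of 42 ribosomal protein genes 1 fell, rpmH, and rplL (-0.47 ± 0.13), rpsB (-1.24 ± 0.36) and rpsU (-0.76 ± 0.23) did not pass. None of 9 OxyR genes passed (sufC at 2.01 ± 0.55, ahpC at 0.71 ± 0.34), nor any of 8 RpoS genes, 2 of anaerobic respiration, 1 of acid resistance and 1 of iron acquisition. The ribosomal RNA list passed camera as higher (adjusted p = 0.0278, and adjusted p = 0.599 with an estimated correlation), with 0 of 9 members past the gene test. With the copies summed the 23S value did not pass (0.26 ± 0.15, adjusted p = 0.368, edgeR). That list call was lost without Con 3 (adjusted p = 0.622), DSS 1 (0.0775), DSS 3 (0.0602) or Lc 3 (0.133), and in the 7 libraries whose number recurs (0.328).

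No gene passed without Lc 2, without Lc 3, with DESeq2 or in a fit of Lc and Con alone, and 180 genes had an unadjusted p under 0.05. The count was 1 without Con 2 or Con 3, 2 without DSS 2, 3 without DSLc 1, 6 without Lc 1, 7 without DSLc 2 and 25 without DSS 1. It was 1 with Lc 2 and Lc 3 summed. In the 7 libraries whose number recurs 4 rose and 7 fell, and 5 of these 11 were among the 14 (tas, mdoD, yibL, erpA and rpmH), and rpsU passed there as well. With total count scaling 5 were higher and 4 lower.

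DSLc against DSS asks what Lc changed in mice given DSS. The carbonic anhydrase gene can, which was higher in DSS than in Con, was lower in DSLc (1184 ± 38.8 CPM, n = 2) than in DSS (3121 ± 1222 CPM, n = 3), and the threonine exporter gene rhtC and the ribosomal protein gene rpmE fell with it. The 23S rRNA share was 9.14% ± 1.23 in DSLc against 13.2% ± 1.04 in DSS. Of 972 genes 0 rose and 3 fell, all with adjusted p = 0.0478 (edgeR quasi-likelihood test): can (-1.42 ± 0.30), rhtC (-3.22 ± 0.72) and rpmE (-1.09 ± 0.24). All 3 were also called higher in DSS than in Con. Both comparisons use the same DSS libraries with opposite sign, which by itself favours such reversals. The excess over the Con mean in DSS 1, 2 and 3 was 3648, 1726 and 1380 CPM for can. It was 1138, 415 and 199 CPM for rhtC, and 1312, 1988 and 592 CPM for rpmE.

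Genes with the smallest p that did not pass were, with positive values in DSLc, ptsI of the sugar phosphotransferase system (1.49 ± 0.35), ybgC (1.85 ± 0.45), the formate dehydrogenase gene fdoG (1.06 ± 0.27), dacD (2.21 ± 0.57) and rplW (2.37 ± 0.64). Negative values were those of ybgE (-1.63 ± 0.39) and rrlG (-0.71 ± 0.17). The ribosomal RNA list passed camera as lower (adjusted p = 7.70e-08, and adjusted p = 0.417 with an estimated correlation). None of its 9 members passed over all genes and 6 did adjusted over the list alone, with rrlC at -1.50 ± 0.38, rrlD at -0.67 ± 0.17 and rrlE at -1.35 ± 0.40. The summed 23S value was -0.72 ± 0.17 (adjusted p = 0.0506, edgeR). Of 42 ribosomal protein genes 1 fell, rpmE, with rplL at -0.44 ± 0.16 and rplP at 1.37 ± 0.52 not passing. Of 9 OxyR genes none passed (oxyR -2.07 ± 0.64, ahpC 0.91 ± 0.40, dps -1.25 ± 0.60 and -0.03 in the 7 libraries whose number recurs, sufC 1.35 ± 0.65), nor did any of 18 for mucus and host sugars (nagE 1.59 ± 0.45), of 8 RpoS genes (tktB 2.03 ± 0.81), of 2 for anaerobic respiration, or the 1 each of acid resistance and iron acquisition.

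The count of 3 became 0 without DSS 1, DSS 2, Lc 2, DSLc 1 or DSLc 2, with DESeq2 and with Lc 2 and 3 summed and DSLc 1 and 2 summed, and 10 to 16 without Con 1, Con 2, Con 3 or Lc 3. It was 56 without DSS 3, 49 in a fit of the 2 groups alone, 24 with a minimum count of 10, 26 with no filter and 35 with the likelihood ratio test, and total count scaling gave 14 higher and 2 lower with a shift of the median by 0.21. In the 7 libraries whose number recurs, with 1 DSLc library, 0 rose and 3 fell. Among these 3 were rrlG (-0.53 ± 0.09) and rrlD (-0.51 ± 0.09, both adjusted p = 0.00173, edgeR), and none was can, rhtC or rpmE.

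DSLc against Lc asks what DSS changed in mice given Lc. No gene passed (edgeR quasi-likelihood test, lowest adjusted p = 0.379), 56 had an unadjusted p under 0.05, and DESeq2 also called 0. Lc 3 and DSLc 1 were closer than independent counts usually are (chi-square ratio 0.825), so the libraries compared may not be independent. The 23S share was 9.99% ± 0.13 in Lc (n = 2) and 9.14% ± 1.23 in DSLc. By library it was 10.1%, 9.11% and 10.7% in Lc 1, Lc 2 and Lc 3. Averaging Lc 2 with Lc 3 hides this spread, so the SD of 0.13 understates it. With the copies summed the 23S value did not pass (-0.16 ± 0.17, adjusted p = 0.994, edgeR). The smallest unadjusted p values belonged to rlmB, an rRNA methyltransferase (-3.43 ± 0.87), and the envelope gene tolA (-2.05 ± 0.53), then yjcE (-1.69 ± 0.52), uup (-1.78 ± 0.56) and yqiA (-1.40 ± 0.45). On the positive side they belonged to dacD (1.89 ± 0.53), ybgC (1.37 ± 0.41), yddW (digH, 1.61 ± 0.52), thrL (0.57 ± 0.21) and glmU (1.04 ± 0.39). None of the 42 ribosomal protein, 18 mucus and host sugar, 9 OxyR, 8 RpoS, 2 anaerobic respiration, 1 acid resistance and 1 iron genes passed, with rplC at -1.22 ± 0.56, rpsG at -0.95 ± 0.44 and manX at -0.87 ± 0.31. The ribosomal RNA list passed camera as lower (adjusted p = 0.0416, and adjusted p = 0.883 with an estimated correlation), and not with total count scaling, in the 7 libraries whose number recurs, or without DSS 1, Lc 3 or DSLc 2.

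DSLc against Con sets both treatments together against neither. No gene passed (edgeR quasi-likelihood test, lowest adjusted p = 0.101), 111 had an unadjusted p under 0.05, and DESeq2 called 0. Smallest p values belonged to rlmB (-3.73 ± 0.85), rplL (-0.70 ± 0.16), ylaB (pdeB, -3.69 ± 0.92), rpmH (-0.59 ± 0.15) and hupB (-0.62 ± 0.16). On the positive side were dacD (2.27 ± 0.59), ybgC (1.73 ± 0.45), fdoG (0.98 ± 0.27), the methylglyoxal synthase gene mgsA (0.89 ± 0.25) and yaiL (1.72 ± 0.49). No member of the 7 fixed lists passed: among their members were nagE (1.56 ± 0.45), eda (-1.27 ± 0.52), sufC (1.42 ± 0.67), tktB (1.92 ± 0.82), uspA (1.01 ± 0.48), rplW (1.70 ± 0.60) and rplM (-0.91 ± 0.33). No list passed camera, though 2 (aerobic respiration and osmotic stress) did without DSLc 2. In the 7 libraries whose number recurs 0 genes rose and 1 fell, rpmH (-0.63 ± 0.13, adjusted p = 0.0170, edgeR), and without DSS 3 the count was 2.

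The interaction asks whether the DSS effect differed with Lc. The protease subunit gene clpX was the only one of 972 to pass: it stood at 5750 ± 1057 CPM in Con, 8854 ± 918 in DSS, 8032 ± 443 in Lc and 5964 ± 131 in DSLc, an interaction of -1.04 ± 0.21 on the log2 scale (adjusted p = 0.0365, edgeR). The ribosomal RNA list had a lower DSS effect with Lc by camera (adjusted p = 1.02e-10, and adjusted p = 0.266 with an estimated correlation), with 0 of 9 members past the test over all genes and 7 adjusted over the list alone (rrlC -2.10 ± 0.52, rrlG -0.93 ± 0.23, rrlD -0.92 ± 0.23, rrlA -1.26 ± 0.36). With the copies summed the 23S interaction was -0.98 ± 0.23 and did not pass (adjusted p = 0.0832, edgeR). Genes that did not pass included tas (-1.43 ± 0.33), ptsI (1.54 ± 0.46), yhbY (0.87 ± 0.28), mtr (1.25 ± 0.40), pepN (1.22 ± 0.41) and alaS (1.18 ± 0.40). In the fixed lists manZ (2.83 ± 0.97), manY (2.14 ± 0.83), fucK (1.84 ± 0.74), rpmH (0.53 ± 0.20), rplT (-0.97 ± 0.37), rplP (1.58 ± 0.64) and rplF (-1.10 ± 0.45) did not pass either. The clpX call was lost without Con 2, Con 3, DSS 1, DSS 2, Lc 2, Lc 3, DSLc 1 or DSLc 2, and with total count scaling, DESeq2, the rRNA genes left out, a non-robust dispersion or either way of summing near-duplicate libraries. It was also lost in the 7 libraries whose number recurs (adjusted p = 0.267, edgeR), where rrlG (-0.60 ± 0.12), rrlD (-0.64 ± 0.12) and tas (-1.72 ± 0.37) passed instead, with 1 DSLc library. The count was 4 without Con 1 and 2 without Lc 1.

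Across the 972 genes, which are not independent replicates, the DSS effects without and with Lc did not correlate (r = 0.02, where 100 regroupings of the libraries gave a mean of 0.00 with SD 0.21), nor did the Lc effects without and with DSS (r = 0.02, regroupings 0.03, SD 0.26). The DSS effect and the Lc effect within DSS were opposed, with r = -0.68. Both use the DSS libraries with opposite sign, and simulated unchanged groups gave -0.41 ± 0.03 (SD). The simulated libraries were independent, while real libraries that share a second number correlated at 0.36 to 0.53, so this SD leaves that resemblance out. Regroupings of the real libraries gave a mean of -0.44 with SD 0.19, and 7 of 100 gave an r as low as the real one. The covariance was -0.53 against a simulated -0.13, a difference of -0.40 that leaves out the same resemblance. With 3 DSS libraries the group cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared libraries.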

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

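The tests of shared peaks, of the evenness of the DSS excess, of scaling, of summed rRNA copies and of the ratio of rRNAs, the simulations and the other splits were chosen or run after the results they bear on were seen.

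A test of the difference itself, the DSS by Lc interaction, singled out clpX (-1.04 on the log2 scale) and the ribosomal RNA list (camera adjusted p = 1.02e-10, and adjusted p = 0.266 with an estimated correlation). The list holds rRNA copies that can share reads, and with the 23S copies summed the interaction did not pass (-0.98 ± 0.23, adjusted p = 0.0832, edgeR). In clpX the DSS libraries lay above Con (0.64 ± 0.14) and the DSLc libraries below Lc (-0.40 ± 0.15), though the latter did not pass (adjusted p = 0.764, edgeR). As given above, the clpX interaction call was lost when most of the single libraries were left out. No group has 4 or more libraries, so no library was tested as an outlier.

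Libraries with the same second number in their name resembled each other across treatments. Genes that peaked in 1 library (at least 8 counts and over 2 times every other library's share, 173 in all) lay at 29.8% of the peak in libraries of another group with the same second number, at 28.3% in libraries of the same group and at 18.9% in libraries sharing neither. The excess at a shared second number was 10.8 percentage points (exact within-group permutation p = 0.00231, one-sided, the smallest that 432 arrangements can give). Treatment alone would not align libraries of different groups by number. The peaks measure again, in the same libraries, the resemblance seen in the correlations, so this p is not separate support. Cross-assignment of reads between libraries that share an index, with the group as the other index, could give levels that are alike along both labels, but the permutation p does not test it separately. A shared cage, litter or handling day could also give the 29.8% at a shared second number and cannot be told apart from it, because the labels do not say what the number means.

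Of the 71 genes higher in DSS, 43 were highest in DSS 1, 25 in DSS 2 and 3 in DSS 3. The median excess over Con in DSS 2 and 3 was 0.678 of that in DSS 1, between the level of shared peaks and an even rise. It was 0.75 or more for 33 genes and 0.5 or less for 28, so spread from DSS 1 stays open for a part of the genes. With total count scaling 90.7% of the 108 genes passed in the same direction, 61 of the 71 higher and 37 of the 37 lower. That scaling lowers the median log2 fold change by 0.17 relative to TMM, so it favours the lower genes and decides nothing for them. Library composition through TMM scaling is argued against as the whole cause only for the higher genes. Simulated libraries with no treatment effect that exchange reads, at the setting closest to the observed shared peaks, gave at most 18 calls for DSS against Con in 20 runs and at most 19 for Lc against Con (medians 5 and 8), and the setting with the most exchange and the widest spread gave at most 64 and 51 (medians 36 and 34), beside 108 and 14 in the data. These settings are assumed, were widened after the first were seen, and exclude nothing. Of the 10 splits of the 6 DSS and Con libraries only 1, the real one, gave 108 genes, the highest other gave 0, and for Lc and Con 1 of 10 gave 14 and the highest other 0, but 10 splits are too few for a share under 0.05.

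The 23S rRNA share was higher in DSS than in Con (13.2% against 8.41%). Splitting of reads between near-identical copies is argued against by the summed copies (adjusted p = 0.00217, edgeR). The lowest DSS ratio of 23S to 16S counts exceeded the highest Con ratio by 1.10. The exact permutation p of this ratio was 0.1, the smallest that DSS against Con allows. The summed 16S value was also positive in DSS, though it did not pass (0.26 ± 0.12, adjusted p = 0.127, edgeR). Whether the counts of both rRNAs follow the number of ribosomes was not tested, so a general gain of ribosomes stays open. Spread from 1 DSS library stays open, since the lowest excess among the DSS libraries was 0.657 of the highest. An effect of DSS on the reporter stays open as well and was not tested separately.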

How the results depend on the processing

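The library-name block, the 7 libraries of recurring numbers, the summed libraries, the summed rRNA copies and the likelihood ratio test were chosen after seeing the data. The library-name block pools 4 libraries that share no number as 1 level. No gene whose value is named for a comparison reversed there under any setting, and of 3714 values 3156 kept their side of the threshold, 355 lost it and 203 gained it. Of the 67 list examples left out of the text, 21 took the opposite sign in at least 1 setting (59 of 1639 values). The cause of the changes below was not tested. For DSS against Con (108 genes) DESeq2 gave 15, the library-name block 215 and the 7 libraries 38 (29 shared). For Lc against Con (14) total count scaling and the replicate block each gave 9, DESeq2 and the 2 groups alone 0, and a minimum count of 10 gave 34. The library-name block gave 98, the 7 libraries 11 (5 shared), Lc 2 and 3 summed 1, both pairs summed 3 and the likelihood ratio test 22. For DSLc against DSS (3) total count gave 16, DESeq2 0, minimum count 10 24, no filter 26, the 2 groups alone 49 and the replicate block 48. It was also 8 with no rRNA, 8 with non-robust dispersion, 65 with the library-name block, 3 (0 shared) in the 7 libraries, 5 with Lc 2 and 3 summed, 0 with both pairs summed and 35 with the likelihood ratio test. For DSLc against Lc (0) the library-name block gave 1. For DSLc against Con (0) minimum count 10 gave 2, the library-name block 27, the 7 libraries 1 and the likelihood ratio test 5. For the interaction (1) total count, DESeq2, no rRNA, non-robust dispersion and both ways of summing gave 0, minimum count 10 gave 5, no filter 8, the library-name block 6, the 7 libraries 3 (0 shared) and the likelihood ratio test 6.

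Leaving out each library gave 12 to 130 genes for DSS against Con, 0 to 25 for Lc against Con, 0 to 56 for DSLc against DSS, 0 to 0 for DSLc against Lc, 0 to 2 for DSLc against Con and 0 to 4 for the interaction. A lone DSLc library was assumed to vary like the other groups. In the 5 comparisons where the ribosomal RNA list passed (1 list each), the estimated correlation and fry gave 0 lists, and for DSLc against Lc total count and the library-name block gave 0. The 7 libraries gave 0 lists for Lc against Con and for DSLc against Lc. List counts without each library were 1 to 1 for DSS against Con, DSLc against DSS and the interaction, 0 to 1 for Lc against Con and DSLc against Lc, and 0 to 2 for DSLc against Con. The whole profile kept p under its threshold in every setting run for it (pseudo-F 1.87 to 2.25 without each library). That held also with permutation within the replicate number (p = 0.0063) and within the library-name number, pooled likewise (p = 0.0016). None of these settings summed the near-duplicate libraries. The correlations ranged without each library from -0.04 to 0.10 and from -0.07 to 0.13 for the 2 comparisons of effects that share no library and from -0.75 to -0.51 for the reversal, and the lowest exact p of library totals from 0.1 to 0.3. The title's replicate numbers did not pair the libraries (correlations of deviations from -0.43 to 0.47, 2 of 11 libraries closest to their own number), and their block changed DSS against Con from 108 to 112. Simulated data at this depth and number of libraries recovered 19.4% of 2-fold and 5.97% of 1.5-fold changes for DSS against Con, and the 2 limits were not varied separately.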

Other observations

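Genes of the following lists and the gene zur were chosen after their values were seen. The envelope stress list had 4 of 18 members higher in DSS than in Con and none lower, namely bamD and smpA (bamE) of the outer-membrane assembly machine, lptD, which places lipopolysaccharide in the outer membrane, and rseC. Their levels in DSS were 2568 ± 417 CPM for bamD (1143 ± 205 in Con), 4412 ± 708 for smpA (2409 ± 636 in Con), 1314 ± 843 for lptD (397 ± 75.6 in Con) and 780 ± 444 for rseC (198 ± 13.8 in Con; SD, n = 3 throughout). As a list it did not pass (camera adjusted p = 0.363). DSS 1 carried much of lptD and rseC: the excess over the Con mean in DSS 1, 2 and 3 was 1891, 414 and 447 CPM for lptD and 1092, 288 and 364 CPM for rseC, and neither passed without DSS 1. Of 10 glycolysis genes 7 did not pass, nor did the list (camera adjusted p = 0.644), with eno higher and pfkA (93.5 ± 42.3 CPM in DSS, 381 ± 93.6 in Con) and pykA (50.5 ± 44.0 in DSS, 320 ± 40.6 in Con) lower. The DSS levels of pfkA and pykA lie under the floor of 3 counts in these libraries (138 to 187 CPM of all counts). Their DSS SDs therefore do not measure the spread between replicates, and the falls rest on very few DSS counts. In the fit of only the 7 libraries whose second library-name number recurs, lptD, rseC, pfkA and pykA did not pass and zur was not kept by the count filter. The aerobic respiration list had 2 of 10 members higher, ybgT and sdhB (camera adjusted p = 0.471).

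Exactly 1 count was found in at least 8 of the 11 libraries for 163 genes, while 100 simulated tables of independent Poisson counts with the same gene shares and totals had 12.2 on average and 22 at most. The gene zur, for a zinc-responsive repressor, had 1 count in each library outside DSS and 13, 5 and 4 counts in the 3 DSS libraries.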
